A study of Mus musculus with 9 samples.

How the data were processed

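RNA was measured in 9 libraries of mouse prostate luminal cells, 3 from each of 3 groups. Per the labels' protocols, cells were sorted as live cells positive for Epcam, Cd24a and EYFP, total RNA was extracted with TRIzol, and polyadenylated RNA was sequenced in pairs. The reporter marked cells in which the tamoxifen-dependent Cre recombinase CreERT2, expressed from Tmprss2, had been active. The intact control group carried Cre and reporter, the Ar deletion group carried a floxed Ar gene as well, and the castration group was collected 5 days after castration. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

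The authors deposited 1 table of raw counts per gene, with 37993 features and 1 column per library. Per the submitters' processing notes, quality was checked with FastQC 0.11.9 and reads were aligned with STAR 2.5.3a, and the labels name the mouse build mm10. The counting tool, its strand setting and the annotation release are not given in the sources used here. Among deposited counts from 1 to 4, 68.8% were even, against 50.4% of counts from 100 to 999, so the mates of a pair appear to have been counted as separate reads. Of the identifiers, 32938 matched the GENCODE M21 annotation of GRCm38, the same assembly as mm10, which supplied symbols and coordinates. Another 5053 did not match and held at most 0.499% of a library's counts, and 2 features were the EYFP and CreERT2 transgenes. No feature lacked a gene identifier, and no column of the table was left out. Genes with near-identical copies, such as the Ifit3, Hba, Hbb, H2 and Svs genes, are uncertain because reads can be divided between copies. The same holds for overlapping and antisense genes, since the strand setting is not known.

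Library totals ran from 45514394 to 51524411 counts. The 3 pairs of libraries within each group correlated at 0.979 to 0.987 on log2 CPM across genes, and their chi-square per degree of freedom was 37.6 to 152, so no 2 libraries agreed within counting noise. Counts were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, and the depth-scaled counts given as CPM are on that scale. Genes with low counts were removed with filterByExpr at a minimum count of 10, which left 15064 genes and removed 22929. Differences between groups were tested with the robust quasi-likelihood F test of edgeR, with all 9 libraries in 1 fit, group as the only term, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0299, a biological coefficient of variation of 17.3%. Standard errors were taken as the absolute log2 fold change divided by the square root of F. Adjusted p-values in the text come from this test unless another is named.

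A set of 31 gene lists was written before the data were examined, as were the design, the other settings to be tried and the rule for naming genes. The lists covered androgen response, secretory proteins, distal and proximal luminal states, other cell types, signalling pathways, stress, cell cycle, metabolism, ribosomal proteins and mitochondrial transcripts. Each list was tested in 3 comparisons with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the 93 tests. Of these, 44 passed the threshold of 0.05, and 0 of the 44 passed when the correlation was estimated from the 9 libraries. The smallest adjusted p with an estimated correlation was 0.182. Fry, which asks whether the genes of a list move one way without setting them against other genes, passed 61 of the 93. Counts of list members are given over all genes tested and adjusted over the list alone.

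Genes were named by a rule. In each comparison with the control it took the 7 largest rises and 7 largest falls among genes past the threshold, with a mean of at least 5 CPM and no overlap between the groups' values, leaving out predicted gene models. It added up to 4 members of each list by adjusted p, and 12 fixed genes whatever their values, namely Ar, Tmprss2, Nkx3-1, Pbsn, Fkbp5, Krt8, Tacstd2, Krt4, Psca, Ly6a, Clu and Krt5. For castration versus Ar deletion it took 5 genes in each direction and up to 2 members of each list. Up to 5 genes called in opposite directions against the control were also allowed.

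The test was checked on simulated counts for Ar deletion versus control, with 200 genes changed among 14512. At absolute log2 changes of 0.5, 1 and 2, edgeR recovered 36.4%, 71.6% and 88.1% of changed genes, and 7.7% of its 142 calls were false. In the same simulation DESeq2 1.42.0 made 178 calls with 20.2% false, and limma-voom made 128 with 3.1% false. Camera called 10 of 10 shifted sets and 0 of 20 unshifted sets.

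The alternatives fixed before the data were examined were size factors from DESeq2, upper-quartile scaling, TMM without the 50 most abundant genes, DESeq2 and limma-voom as tests, no filter on low counts, a minimum of 5 CPM in 3 libraries, fits of only the groups compared, a block for the replicate number, a minimum fold change of 2, an adjusted p threshold of 0.01, and each library left out in turn. A further 3 were added after the data were seen. One divided each deposited count by 2 and rounded up, and is called each read pair counted once below. No reads were recounted, and many counts were odd, so it only approximates a count of pairs. Another left out the libraries highest in Svs1, control replicate 2 and Ar deletion replicate 1, which were not the highest 2 in all Svs genes together (7.65% and 5.81% of counts, against 6.46% in control replicate 3). The last left out the library of each group with the most Krt15, a basal marker, namely control replicate 1, Ar deletion replicate 1 and castration replicate 2, and so chose libraries on a measured marker. Unchanged groups were simulated against the same control libraries 20 times to give the correlation that shared controls alone produce.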

Results

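Gene expression was measured by RNA-seq in luminal cells of the mouse prostate, the secretory epithelial cells that express the androgen receptor, encoded by Ar. Cells were sorted by the EYFP reporter that Cre had switched on in Tmprss2-expressing cells. There were 3 libraries from intact control mice and 3 from intact mice in which Ar was deleted in the marked cells. Another 3 came from mice 5 days after castration, which removes the main source of androgen. All 9 libraries were taken 2 weeks after induction of the reporter. The question was which changes follow from loss of the receptor within luminal cells and which from loss of androgen in the whole animal. The time since the loss (up to 2 weeks against 5 days) and the floxed line differed along with the kind of loss. The comparisons cannot separate these. Total counts were 48342022, 50260836 and 49900069 in the control libraries, 48616801, 50112619 and 45514394 in the Ar deletion libraries, and 50337240, 50231043 and 51524411 in the castration libraries. The first 2 principal components held 42.2% and 25.7% of the variance. One transcript, 9530053A07Rik, took 21.5% ± 1.01 (SD, n = 3) of the control counts, 2.08% ± 0.676 after Ar deletion and 5.85% ± 1.46 after castration.

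Ar (ENSMUSG00000046532, chromosome X, 98148769 to 98323215, plus strand, GRCm38) stood at 60.5, 58.2 and 64.4 CPM in control replicates 1 to 3. In the Ar deletion libraries it stood at 34.6, 37.5 and 37.4 CPM, and in the castration libraries at 129, 119 and 132 CPM. Every Ar deletion library lay below every control library, and the group mean was 59.8% of the control mean (log2 fold change -0.74 ± 0.07 SE, adjusted p = 4.72e-06). After castration Ar rose 2.07-fold (log2 fold change 1.05 ± 0.07 SE, adjusted p = 6.15e-07). The labels do not say which exon was removed, and counts are per gene, so counts from the remaining exons may be included and the value does not measure the efficiency of deletion. The EYFP transcript was 6011 ± 282 CPM in the controls, 2634 ± 687 after Ar deletion (log2 fold change -1.19, adjusted p = 0.000286) and 5160 ± 462 after castration (adjusted p = 0.325).

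**Figure D1:**
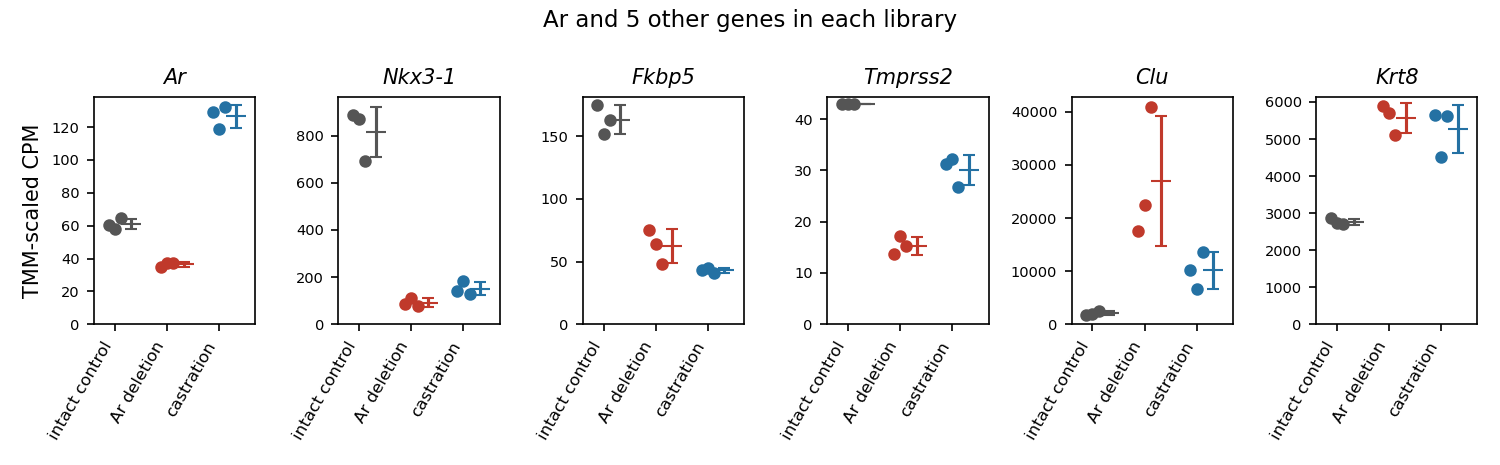
Depth-scaled counts (CPM with TMM factors) of Ar, Nkx3-1, Fkbp5, Tmprss2, Clu and Krt8 in the 9 libraries, by group, with points for single libraries and bars for the mean ± SD of 3. Ar averaged 61.1 CPM in the controls, 36.5 CPM after Ar deletion and 127 CPM after castration, while Nkx3-1 averaged 816, 91.9 and 151 CPM.

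After deletion of Ar in luminal cells of intact mice, 6 of 10 secretory protein genes fell, and 7 of 11 basal markers and 16 of 22 immediate early and stress genes rose. These list calls were lost with an estimated correlation (adjusted p = 0.182, 0.435 and 0.199). Nkx3-1, a prostate homeobox gene and androgen receptor target, fell 8.88-fold, from 816 ± 110 to 91.9 ± 18 CPM (SD, n = 3). Tgm4, which encodes the prostate transglutaminase, fell 8.18-fold, and Pbsn, encoding probasin, fell 4.16-fold. Clu, encoding the secreted chaperone clusterin, rose 13.0-fold, and Cd44, encoding a hyaluronan receptor, rose 20.2-fold. In all, 3506 genes rose and 3224 fell among 15064 tested, and 1403 and 633 of these changed by at least 2-fold.

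Of the 10 secretory protein genes, 6 fell and 0 rose, with the same numbers adjusted over the list alone (camera adjusted p = 9.31e-06; adjusted p = 0.182 with an estimated correlation). Pbsn (log2 fold change -2.06 ± 0.16 SE), Tgm4 (-3.03 ± 0.24), Apof (-2.36 ± 0.24) and Azgp1 (-1.30 ± 0.15) were among them. Ar deletion replicate 3 stood apart in Sbp, at 664 CPM against 15400 and 10700 CPM in the other Ar deletion libraries, and in Spink1, at 86.0 against 1650 and 1350 CPM. Neither gene passed, and without this library the list gave a camera adjusted p = 1.92e-05. Genes for protein folding and export through the endoplasmic reticulum fell together, 33 of 36 against 2 that rose, and likewise adjusted over the list alone (camera adjusted p = 2.46e-16; adjusted p = 0.182 with an estimated correlation). They included Dnajc3, a co-chaperone, which fell 2.67-fold, Lman1, a cargo receptor (-1.23 ± 0.08), Sec11c, a signal peptidase subunit (-1.15 ± 0.07), and Sel1l, a component of protein disposal from the reticulum (-1.12 ± 0.07). Of 58 oxidative phosphorylation genes, 29 fell and 0 rose, as adjusted over the list alone, with a median log2 fold change of -0.19 (camera adjusted p = 0.000185; adjusted p = 0.586 with an estimated correlation). Ndufa1, a subunit of complex I, fell by 0.83 ± 0.07 on the log2 scale, and Uqcrq, of complex III, fell by 0.76 ± 0.08.

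Of 15 distal luminal identity genes, 6 fell and 2 rose, against 6 and 3 adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.182 with an estimated correlation). The list's median log2 fold change was -0.13, but 0.01 without control replicate 2 and 0.08 without the libraries highest in Svs1. Nkx3-1, Tmprss2 (2.80-fold), Bmpr1b (log2 fold change -1.02 ± 0.08 SE) and Pbsn fell, whereas the luminal keratin genes Krt8 (1.01 ± 0.09) and Krt18 (0.87 ± 0.10) rose. The androgen response list held 26 genes that rose and 29 that fell among 79, against 28 and 32 adjusted over the list alone, and did not pass (camera adjusted p = 0.205, and adjusted p = 0.0188 with fry). Its median log2 fold change was -0.09 and its mean 0.07, opposite in sign, and the test pointed downward. Fkbp5, a chaperone of steroid receptors, fell 2.60-fold (adjusted p = 1.76e-05), while Arid5b rose 2.88-fold. Of these 79 genes, 21 stood on another list too.

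Of 15 proximal luminal or progenitor genes, 6 rose and 0 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00297; adjusted p = 0.428 with an estimated correlation). Cd44 (log2 fold change 4.34 ± 0.26 SE), Clu (3.70 ± 0.43), Ly6a (1.57 ± 0.26), encoding Sca-1, and Tacstd2 (2.03 ± 0.40), encoding Trop2, rose. Krt4 (1.01 ± 0.99, adjusted p = 0.455) and Psca (-0.52 ± 0.94, adjusted p = 0.691) did not pass. The list's median of 1.57 was 0.39 without Ar deletion replicate 1, where it still passed (camera adjusted p = 0.00901). That library held the most of the basal marker Krt15 (697 CPM, against 96.6 and 280 CPM in the other Ar deletion libraries). Whether a larger share of basal cells added to the rise of the proximal genes was not tested. Of 11 basal epithelial markers, 7 rose and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.435 with an estimated correlation). Krt14 rose 6.82-fold, Krt17 10.6-fold and Itgb4, encoding an integrin of the basal surface, 2.87-fold, while Krt5 spread widely between libraries (177 ± 120 CPM against 34.5 ± 32, adjusted p = 0.187, and 0.0324 with limma-voom).

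Markers of other cells moved too. Of 8 smooth muscle markers, 5 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.00719; adjusted p = 0.573 with an estimated correlation), with Smtn at 33.6 ± 2.3 against 7.80 ± 1.0 CPM and Tagln at 27.1 ± 3.0 against 12.4 ± 0.71 CPM. Of 9 fibroblast markers, 3 rose and 0 fell, and 5 rose adjusted over the list alone (camera adjusted p = 0.092, and adjusted p = 0.0155 with fry). Col1a1 rose from 4.25 ± 0.53 to 12.2 ± 3.8 CPM. Markers of ionocytes, epithelial cells rich in proton pumps, fell for 6 of 7 with 0 rising, as adjusted over the list alone (camera adjusted p = 0.000267; adjusted p = 0.227 with an estimated correlation). Foxi1, the transcription factor of these cells, fell from 38.9 ± 9.1 to 8.57 ± 1.6 CPM and Atp6v1b1 from 12.4 ± 2.0 to 4.57 ± 0.19 CPM.

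Notch pathway genes rose for 8 of 10 and fell for 1, as adjusted over the list alone (camera adjusted p = 0.00013; adjusted p = 0.182 with an estimated correlation). Heyl rose 9.73-fold, Hes1 3.71-fold, Notch3 3.15-fold and Jag1 2.83-fold, beside the higher smooth muscle markers given above. Targets of YAP, a coactivator of the Hippo pathway, rose for 9 of 11 and fell for 1, as adjusted over the list alone (camera adjusted p = 9.31e-06; adjusted p = 0.182 with an estimated correlation). Ccn1 rose 4.48-fold, Ptpn14 3.62-fold and Amotl2 2.79-fold. Of 22 immediate early and stress genes, 16 rose and 3 fell, against 16 and 4 adjusted over the list alone (camera adjusted p = 4.92e-08; adjusted p = 0.199 with an estimated correlation), among them Zfp36 (3.57-fold), Nr4a1 (2.77-fold) and Junb (2.45-fold). This list also responds to the handling of tissue.

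Targets of NF-kB, a transcription factor of inflammation, rose for 16 of 22 and fell for 2, against 16 and 3 adjusted over the list alone (camera adjusted p = 2.85e-06; adjusted p = 0.337 with an estimated correlation). Relb rose 3.48-fold and Nfkb2 2.16-fold. Antigen presentation genes rose for 15 of 19 and fell for 1, against 17 and 1 adjusted over the list alone (camera adjusted p = 0.000568; adjusted p = 0.263 with an estimated correlation), with Psmb8, an immunoproteasome subunit, up 2.47-fold. Of 30 interferon response genes, 15 rose and 5 fell, as adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.651 with an estimated correlation). That call was lost without control replicate 2, control replicate 3 or Ar deletion replicate 1 (adjusted p from 0.0596 to 0.139), and without the top basal library of each group (adjusted p = 0.0722), without the libraries highest in Svs1 (adjusted p = 0.222) or with each pair counted once (adjusted p = 0.0507). Leukocyte markers stood lower for 2 of 13 and higher for 0, as adjusted over the list alone (camera adjusted p = 0.16). Of 28 cell cycle genes, 8 rose and 1 fell, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.711 with an estimated correlation). That call was lost without control replicate 1, control replicate 2, Ar deletion replicate 2 or Ar deletion replicate 3 (adjusted p from 0.0749 to 0.138). Mcm3, Mcm5 and Mcm6, of the DNA replication helicase, rose 2.68, 2.93 and 2.14-fold.

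The largest rises by the naming rule included Cadps, which encodes an activator of vesicle release and rose from 1.03 ± 0.058 to 172 ± 4.7 CPM (chromosome 14, 12372563 to 12823079). Olfm4, encoding olfactomedin 4, rose from 1.23 ± 0.21 to 138 ± 62 CPM, Klk1, a tissue kallikrein of a family with similar copies, from 0.113 ± 0.029 to 22.7 ± 9.4 CPM, and Cyp1a1, a target of the aryl hydrocarbon receptor, from 0.726 ± 0.24 to 39.8 ± 9.5 CPM. The largest falls included Slc9a3, encoding a sodium and proton exchanger, 111-fold, to 0.202 ± 0.19 CPM (log2 fold change -6.79, and -7.88 without Ar deletion replicate 2). Saa1, a serum amyloid A gene with similar copies, fell from 15.5 ± 1.3 to 0.159 ± 0.14 CPM (log2 fold change -6.56, and -7.62 without Ar deletion replicate 2). Aldh1l2, a mitochondrial folate enzyme, fell 21.6-fold. Another 336 predicted gene models passed the threshold and were not named under the rule. For 8312 genes (55.2%), the 3 values of one group lay wholly on one side of the other 3, where chance gives 10%.

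After castration 7 of 10 secretory protein, 18 of 24 cholesterol synthesis and 20 of 28 cell cycle genes fell, and 19 of 30 interferon response genes rose. These list calls were lost with an estimated correlation (adjusted p = 0.182, 0.182, 0.312 and 0.247). Nkx3-1 fell 5.41-fold, from 816 ± 110 to 151 ± 28 CPM (SD, n = 3), Tgm4 fell 5.04-fold and Fkbp5 3.81-fold. Ccnb1, encoding cyclin B1, which drives entry into mitosis, fell 13.1-fold. Clu rose 4.91-fold, and Ifit3, an interferon-induced gene with the near copy Ifit3b, rose 27.0-fold. In all, 2616 genes rose and 2521 fell among 15064, and 744 and 731 of these changed by at least 2-fold.

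Of the 10 secretory protein genes, 7 fell and 0 rose, as adjusted over the list alone (camera adjusted p = 3.87e-08; adjusted p = 0.182 with an estimated correlation). Msmb, encoding beta-microseminoprotein, fell 6.10-fold, and Apof fell by 3.04 ± 0.25 on the log2 scale. Pbsn fell 1.43-fold (log2 fold change -0.52 ± 0.15 SE, adjusted p = 0.0277), a call lost without control replicate 1, control replicate 2 or castration replicate 1 (adjusted p from 0.0654 to 0.0828), with no filter on low counts (adjusted p = 0.0936) and without the libraries highest in Svs1 (adjusted p = 0.0699). Of 36 genes of folding and export, 31 fell and 2 rose, as adjusted over the list alone (camera adjusted p = 1.2e-14; adjusted p = 0.182 with an estimated correlation), with Dnajc3 down 2.16-fold. Of 58 oxidative phosphorylation genes, 15 fell and 0 rose, as adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.698 with an estimated correlation). That list's call was lost without the top basal library of each group (adjusted p = 0.0737).

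Of 24 cholesterol synthesis genes, 18 fell and 0 rose, and 19 fell adjusted over the list alone (camera adjusted p = 4.29e-15; adjusted p = 0.182 with an estimated correlation). Idi1, an isoprenoid enzyme, fell 4.93-fold, Insig1, a sterol sensor, 3.73-fold, and Hmgcr, the rate-limiting enzyme, fell by 1.29 ± 0.09 on the log2 scale. After Ar deletion 10 of these genes fell and 3 rose, as adjusted over the list alone (camera adjusted p = 0.0507). That list passed with DESeq2 size factors (adjusted p = 0.0495), fry (0.0188), without control replicate 3 (0.043), Ar deletion replicate 1 (0.0146) or Ar deletion replicate 2 (0.036), without the libraries highest in Svs1 (0.0236) and without the top basal library of each group (0.0308). Of 28 cell cycle genes, 20 fell and 1 rose after castration, against 21 and 1 adjusted over the list alone (camera adjusted p = 4.43e-11; adjusted p = 0.312 with an estimated correlation). Ccnb1 stood at 0.183 ± 0.032 against 2.43 ± 0.84 CPM, Plk1, a mitotic kinase, at 0.165 ± 0.017 against 2.30 ± 1.0 CPM, and Mcm6 rose 1.43-fold. Of 12 Wnt target genes, 3 fell and 2 rose, against 4 and 2 adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.479 with an estimated correlation). Nkd1, which also restrains the Wnt pathway, fell 3.38-fold after Ar deletion and 4.01-fold after castration.

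Interferon response genes rose for 19 of 30 and fell for 1, against 20 and 1 adjusted over the list alone (camera adjusted p = 8.36e-09; adjusted p = 0.247 with an estimated correlation). Oasl2 rose 3.46-fold, Parp14 2.29-fold and Irf9 2.12-fold. Antigen presentation genes rose for 11 of 19 and fell for 1, against 12 and 1 adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.182 with an estimated correlation), with Psmb8 up 2.98-fold. Leukocyte markers rose for 0 of 13 and fell for 1, as adjusted over the list alone (camera adjusted p = 0.215). The marker that fell was Cd52, down 21.9-fold. Targets of NF-kB rose for 11 of 22 and fell for 4, as adjusted over the list alone (camera adjusted p = 0.00685; adjusted p = 0.565 with an estimated correlation). Immediate early and stress genes rose for 16 of 22 and fell for 0, and 17 rose adjusted over the list alone (camera adjusted p = 4.41e-11; adjusted p = 0.182 with an estimated correlation), with Zfp36 up 3.01-fold. YAP targets rose for 5 of 11 and fell for 0, as adjusted over the list alone (camera adjusted p = 0.000801; adjusted p = 0.276 with an estimated correlation). The Notch list, with 4 of 10 rising and 0 falling, as adjusted over the list alone, did not pass (camera adjusted p = 0.0544). It passed with the replicate block (adjusted p = 0.0423), fry (0.0111) and without control replicate 3 (0.0354), castration replicate 1 (0.034) or castration replicate 3 (0.0431).

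Krt8 rose 1.91-fold and Krt18 1.73-fold after castration, and Tmprss2 fell 1.43-fold. Of 15 distal luminal genes, 6 fell and 4 rose, as adjusted over the list alone (camera adjusted p = 0.2, and adjusted p = 0.00804 with fry). Of 79 androgen response genes, 25 fell and 18 rose, against 25 and 19 adjusted over the list alone (camera adjusted p = 0.053). That list passed with DESeq2 size factors (adjusted p = 0.0495), fry (0.00213) and without control replicate 3 (0.0224). Of 15 proximal luminal genes, 5 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.11). The proximal list passed with the replicate block (adjusted p = 0.0239), fry (0.0494), without control replicate 1 (0.03) or castration replicate 1 (0.0379), and without the top basal library of each group (adjusted p = 0.0436). Its median was 0.33, but -0.16 without control replicate 2, -0.31 without castration replicate 2 and -0.16 without the libraries highest in Svs1. Cd44 rose 3.19-fold and Ly6a did not pass (log2 fold change -0.32 ± 0.25 SE). Tacstd2 rose 2.60-fold (adjusted p = 0.0355), a call lost without control replicate 3 or any 1 of the castration replicates (adjusted p from 0.0656 to 0.102), with no filter on low counts (adjusted p = 0.0557) and in a fit of only the groups compared (adjusted p = 0.0647). Of 11 basal markers, 2 rose and 0 fell, and 1 rose adjusted over the list alone (camera adjusted p = 0.582), with a median of -0.04 and a mean of 0.08. Krt5 stood at 28.5 ± 36 against 34.5 ± 32 CPM.

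Smooth muscle markers fell for 6 of 8 and rose for 1, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.586 with an estimated correlation). The median of -1.46 was -2.12 without castration replicate 3, and the call was lost without the top basal library of each group (adjusted p = 0.121). Fibroblast markers fell for 3 of 9 and rose for 0, and 4 fell adjusted over the list alone (camera adjusted p = 0.0455; adjusted p = 0.554 with an estimated correlation). That call was lost without control replicate 1, control replicate 3, castration replicate 1 or castration replicate 2 (adjusted p from 0.114 to 0.134, medians from -0.93 to -0.73), and with each alternative added after the data were seen (adjusted p = 0.0631 with pairs counted once, 0.0527 without the libraries highest in Svs1 and 0.174 without the top basal library of each group). Col1a1 fell to 1.41 ± 0.48 CPM. Of 7 ionocyte markers, 2 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.38).

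By the naming rule the largest rises after castration included Cadps (22.7-fold), Cxcl15, a chemokine gene (15.5-fold), and Galnt9, a glycosyltransferase gene (50.6-fold). The largest falls included Cuzd1 (58.5-fold), Plekhg4 (46.5-fold) and Defb42, a beta-defensin gene with similar copies (29.3-fold). Slc9a3 fell 18.9-fold. Another 259 predicted gene models passed the threshold. For 7506 genes (49.8%) the groups' values did not overlap, where chance gives 10%.

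**Figure D2:**
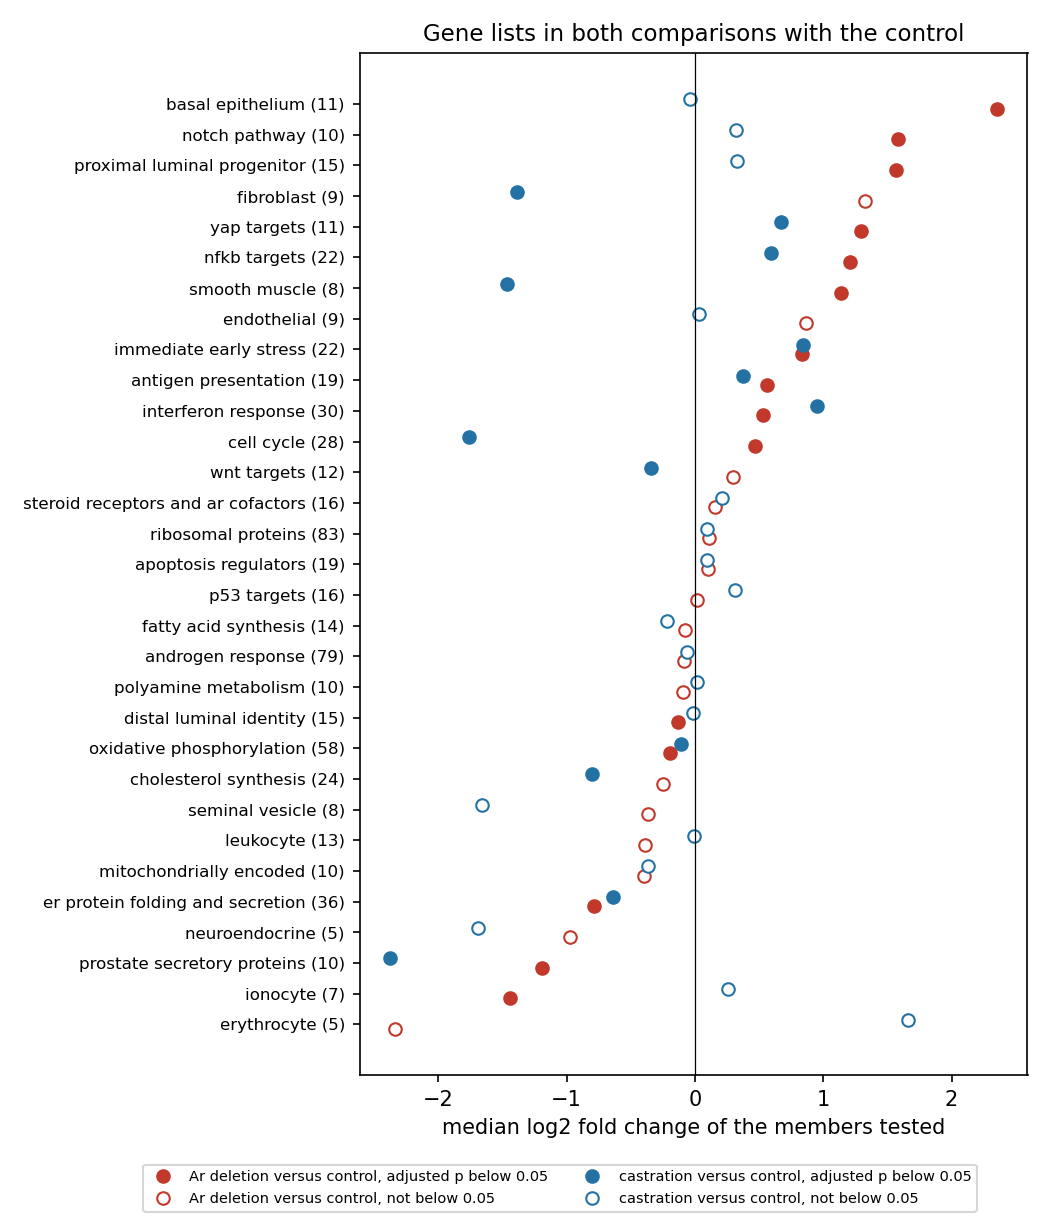
Median log2 fold change of the 31 gene lists in Ar deletion versus control and castration versus control, with filled symbols for lists at a camera adjusted p under 0.05 with the preset correlation. The cell cycle list lies at 0.47 after Ar deletion and -1.76 after castration, and the ionocyte list at -1.44 and 0.25.

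Both effects shared many genes: 3811 genes changed the same way in both comparisons with the control, 1983 rising and 1828 falling. Nkx3-1, Tgm4 and Dnajc3 fell and Clu, Krt8 and Hes1 rose in both. Independent lists of the same sizes would share 609 rising and 540 falling genes. Another 79 genes changed in opposite directions, 2840 passed only after Ar deletion and 1247 only after castration, which does not show that these differ between the treatments. Across genes, which are not independent replicates, both effects correlated at r = 0.638 (Spearman's rho 0.674), with a covariance of 0.564. Both comparisons used the same controls. Unchanged groups simulated against them gave r = 0.502 (0.426 to 0.573 over 20 simulations), a covariance of 0.0546 and 0 genes called in both. The difference of the covariances was 0.509. The 3 controls cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

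**Figure D3:**
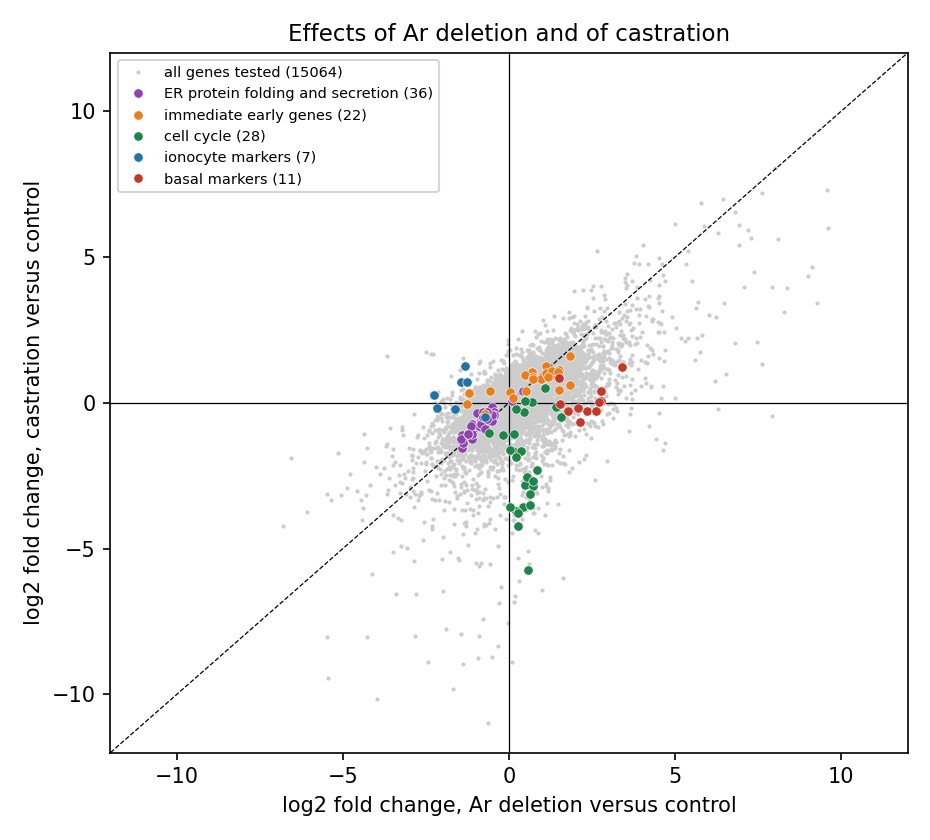
Log2 fold change of each tested gene after Ar deletion (horizontal axis) and castration (vertical axis), each against the same controls, with members of 5 gene lists coloured. Both effects correlated at r = 0.638 across 15064 genes.

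Set directly against each other, castration and Ar deletion differed in 26 of 28 cell cycle genes, 7 of 9 fibroblast, 8 of 8 smooth muscle, 7 of 11 basal and 6 of 7 ionocyte markers. These list calls were lost with an estimated correlation (adjusted p = 0.182, 0.182, 0.182, 0.308 and 0.182). Ccnb1 was 15.1-fold lower after castration than after Ar deletion (0.183 ± 0.032 against 2.80 ± 0.78 CPM), and Col1a1 was lower by a log2 difference of -3.12 ± 0.27 SE. Foxi1 was higher after castration (log2 difference 2.00 ± 0.21 SE). Pbsn was 2.91-fold and Ar 3.47-fold higher after castration, and Tmprss2 was higher by a log2 difference of 0.97 ± 0.10 SE. The time since the loss and the floxed line differ in this comparison as well. In it 1490 genes were higher and 1781 lower after castration. Without castration replicate 1 these counts were 853 and 1129. Without the top basal library of each group, chosen by Krt15 after the data were seen, they were 681 and 1152. At a fold of at least 2 they were 170 and 813, a share of higher genes of 17.3% rather than 45.6%. Of the 3811 genes changed alike against the control, 1020 also differed here, and 795 of these changed more after Ar deletion.

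Cell cycle genes were lower after castration for 26 of 28 and higher for 0, and 27 were lower adjusted over the list alone (camera adjusted p = 1.76e-32; adjusted p = 0.182 with an estimated correlation). Cholesterol synthesis genes were lower for 16 of 24 and higher for 1, against 19 and 1 adjusted over the list alone (camera adjusted p = 1.71e-12; adjusted p = 0.182 with an estimated correlation). Interferon genes were higher for 11 of 30 and lower for 1, against 15 and 2 adjusted over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.373 with an estimated correlation). NF-kB targets were lower for 9 of 22, and 12 adjusted over the list alone (camera adjusted p = 0.000175; adjusted p = 0.441 with an estimated correlation). Notch genes were lower for 6 of 10, and 7 adjusted over the list alone (camera adjusted p = 0.000393; adjusted p = 0.202 with an estimated correlation). Wnt targets were lower for 4 of 12, against 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00269; adjusted p = 0.371 with an estimated correlation). YAP targets were lower for 5 of 11 and higher for 1, as adjusted over the list alone (camera adjusted p = 0.0142; adjusted p = 0.428 with an estimated correlation), a call lost without Ar deletion replicate 3 (adjusted p = 0.0621).

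Smooth muscle markers were lower for 8 of 8, as adjusted over the list alone (camera adjusted p = 4.48e-14; adjusted p = 0.182 with an estimated correlation), with a median of -2.45 that was -3.23 without castration replicate 3. Fibroblast markers were lower for 7 of 9, and 8 adjusted over the list alone (camera adjusted p = 9.11e-08; adjusted p = 0.182 with an estimated correlation). Basal markers were lower for 7 of 11, and 8 adjusted over the list alone (camera adjusted p = 1.23e-07; adjusted p = 0.308 with an estimated correlation). Proximal luminal genes were lower for 3 of 15 and higher for 1, against 4 and 1 adjusted over the list alone (camera adjusted p = 0.00719; adjusted p = 0.473 with an estimated correlation), and their median of -1.16 was -0.35 without Ar deletion replicate 1. Ionocyte markers were higher for 6 of 7, as adjusted over the list alone (camera adjusted p = 1.71e-12; adjusted p = 0.182 with an estimated correlation). Distal luminal genes were higher for 5 of 15 and lower for 1, as adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.182 with an estimated correlation). Folding and export genes were higher for 9 of 36, and 12 adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.586 with an estimated correlation), a call lost without castration replicate 1 (adjusted p = 0.0621). Oxidative phosphorylation genes were higher for 8 of 58, and 1 adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.698 with an estimated correlation), a call lost without Ar deletion replicate 3 or castration replicate 1 (adjusted p from 0.0569 to 0.0851) and with fry (adjusted p = 0.0708). The largest falls by the naming rule included Ly6c1, of a family with similar copies, at 1.99 ± 0.37 CPM after castration against 75.2 ± 7.3 CPM after Ar deletion. For 5761 genes (38.2%) the values of both groups did not overlap, where chance gives 10%, and 132 predicted gene models passed.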

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

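All tests of explanations in this part, and the splits of the libraries, were chosen or had their outcomes stated after the results they bear on had been seen. The results below were taken up because both effects against the control differed in sign, by the calls for genes and by the medians alone for lists. The contrast of castration and Ar deletion gives the size of the difference.

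After Ar deletion and after castration, 79 genes changed in opposite directions. Each also passed in castration versus Ar deletion, which follows from how they were picked and is no separate test of them. A ranking by that contrast left out predicted gene models, unmatched identifiers, immunoglobulin and T-cell receptor segments and the transgenes. Among the rest of these 79, the 5 smallest adjusted p-values belonged to Ar (log2 difference 1.79), Atp6v1b1 (2.15), Hexb (1.25), Cyp51 (-1.75) and Exph5 (1.39). Among the lists, median log2 differences of castration from Ar deletion were -2.35 for basal, 2.00 for ionocyte, -2.25 for fibroblast, -2.45 for smooth muscle, 4.001 for erythrocyte, -2.06 for cell cycle and -0.44 for Wnt target genes. These list calls were lost with an estimated correlation (adjusted p from 0.182 to 0.371). Against the control, the basal, ionocyte and erythrocyte lists did not pass after castration (camera adjusted p = 0.582, 0.38 and 0.196). The fibroblast, erythrocyte and Wnt lists did not pass after Ar deletion (camera adjusted p = 0.092, 0.16 and 0.992). Opposite effects were therefore not shown for these lists. For the cell cycle and smooth muscle lists they rest on unsteady calls. The cell cycle rise after Ar deletion (camera adjusted p = 0.0494) was lost with any 1 of 4 libraries left out. The smooth muscle fall after castration (camera adjusted p = 0.0141) was lost without the top basal library of each group (adjusted p = 0.121). The basal median after castration was -0.04, with a mean of 0.08. The erythrocyte list rested on 5 genes, 4 of them globin genes with near-identical copies, with a camera adjusted p = 0.00033 (adjusted p = 0.312 with an estimated correlation) and 4 genes higher over all genes and adjusted over the list alone. Its median was 3.00 without castration replicate 2.

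Ar counts remained at 59.8% of the control mean in the Ar deletion group, with a 95% interval from 54.3% to 65.9%. Marked cells that kept an intact gene would hold every other transcript at their own share or above, if their levels were those of the controls. Among 6437 genes of at least 20 CPM in the controls, 193 had an upper bound below the lower bound of Ar, with Slc9a3 at 0.902% (upper bound 1.67%) and Nkx3-1 at 11.3% (upper bound 14.6%). This argues against unrecombined cells as the whole source of the remaining counts. Transcript from outside the deleted part stays open and cannot be told apart, because the table holds 1 value for the whole gene, and a higher output of the recombined gene was not tested.

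In the Ar deletion group 7 of 11 basal, 5 of 8 smooth muscle and 3 of 9 fibroblast markers were higher and 0 lower. Of 9 endothelial markers 1 was higher and 1 lower. The fibroblast list did not pass (camera adjusted p = 0.092). The basal and smooth muscle calls were lost with an estimated correlation (adjusted p = 0.435 and 0.573). A larger share of basal cells may add to the rise of the basal markers. With log2 Krt15 as a covariate, the median log2 fold change of the 10 other basal markers went from 2.49 to 1.39. The 7 of those markers that passed before also passed with the covariate, and 9 passed in all. Krt15 is 1 marker that spread widely within groups (123 ± 107 CPM in the controls), so it may capture basal content only in part. Whether a larger basal share is the whole cause is not decided by this test. A lower share of luminal cells would raise markers of every other type. The ionocyte median was -1.44, but it cannot decide this, because a change within cells may also have lowered those markers. A lower share of luminal cells and a change of state in the recombined cells stay open. More stromal cells stay open too, although the gate on Epcam, Cd24a and EYFP would exclude cells without these markers. Here 0 of the 11 basal markers stood on another list, though 10 of them were at 1 CPM or more in the controls.

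Of 7 ionocyte markers, 6 were lower in the Ar deletion group, a list call lost with an estimated correlation (adjusted p = 0.227). If fewer ionocytes were sorted, the markers would be expected to fall by a common factor. Cochran's Q across the markers' edgeR estimates, set against a chi-square distribution as an approximation, gave p = 0.0112 for unequal changes. The log2 fold changes ran from -2.26 to -0.72. Expression of some markers in luminal cells would also make the changes unequal, so a smaller share of ionocytes and a change within cells cannot be told apart here. Of the 7 markers, 5 stood at 1 CPM or more in the controls, the highest at 38.9 CPM, and 0 were on another list. Whether the gate on Epcam, Cd24a and EYFP excludes ionocytes is not known here.

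For each comparison, 1 of the 10 splits of its 6 libraries into 3 and 3 gave as many genes as the real one, which was the real split. The real counts were 6730, 5137 and 3271, and the highest of the other splits was 0 in each. With 10 splits no share under 0.05 can be reached.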

How the results depend on the processing

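Most alternatives were planned, and the 3 settings named here as added were chosen after the data were seen. No call changed direction in its test. List medians took the other sign in 49 recomputations, over 18 lists and contrasts. Only 1 of these was called, the distal luminal list after Ar deletion, which still passed with the test downward at a median of 0.01 without control replicate 2 and 0.08 without the libraries highest in Svs1. Among those not called after Ar deletion, the seminal vesicle median went from -0.37 to 2.57 without control replicate 2. The neuroendocrine median went from -0.97 to 0.79 without control replicate 3 and to 1.86 with each read pair counted once. Counts and the correlation stayed within 1.5 times of their values, or within their spread, in 212 recomputations and moved further in 23. List tests kept their side of the threshold in 1190 recomputations, gained a call in 44 and lost one in 68, of which 44 came with an estimated correlation. Named genes kept their side in 5663, gained a call in 12 and lost one in 181. At a fold of at least 2, fewer genes passed by construction: 2036 after Ar deletion (1403 higher, 633 lower), 1475 after castration (744 and 731), 983 between treatments (170 and 813) and 891 in both. At an adjusted p under 0.01 there were 3337 after castration (1686 and 1651), 1604 between treatments (668 and 936) and 2490 in both. With a library left out, counts ran from 5615 to 6325 after Ar deletion (2900 to 3256 higher, 2715 to 3069 lower), 4047 to 4525 after castration (2032 to 2282 and 2005 to 2243), 1982 to 3159 between treatments (853 to 1492 and 1129 to 1667, lowest without castration replicate 1) and 2994 to 3811 in both, and r from 0.572 to 0.678. Ar stood at 58.4% to 61.4% of the control.

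The added setting without the top basal library of each group leaves 2 libraries a group and was picked on measured Krt15. It gave 5321, 3840 and 1833 genes (the last 681 higher and 1152 lower, moved by over 1.5 times), ended 25 gene calls and 4 list calls and added 6 list calls. With fewer libraries some loss follows, and the rest of the cause was not tested. The other added settings gave 6727, 5126 and 3373 genes with pairs counted once, and 5120, 4112 and 2467 without the libraries highest in Svs1. At this depth and n, the simulation recovered 36.4% of changes of 0.5 on the log2 scale. In it edgeR called 142 of 14512 genes. The real data gave 6730 of 15064 after Ar deletion, 5137 after castration and 3271 between treatments. With fewer changed genes the adjusted threshold is stricter, so the simulated rate need not hold for the real comparisons. Small changes can be missed in these too, at a rate that was not measured.

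With the replicate number as a block there were 6619, 5037 and 3140 genes, 3767 in both, and r was 0.645. The correlation of same-numbered libraries' deviations ran from -0.222 to 0.164. Between control and Ar deletion each library correlated best with its own number (0.164, 0.099 and 0.051, against -0.112 to 0.02 for other numbers). Between control and castration, replicates 1 and 2 gave -0.11 and -0.222 with their own number. In both other groups at once, 2 of 9 libraries correlated best with their own number. Whether the numbers pair the libraries is therefore not settled.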

Other observations

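No explanation was tested in this part. Genes listed as markers of the seminal vesicle, a gland next to the prostate, were abundant. Svs1 and the list's median were uneven between libraries, and Svs2 less so. Which cells these transcripts came from was not tested. Of 8 such genes 0 rose and 1 fell after Ar deletion (camera adjusted p = 0.616) and 0 rose and 2 fell after castration (adjusted p = 0.159), as adjusted over the list alone. The list passed after castration without the top basal library of each group (adjusted p = 0.0436). In castration versus Ar deletion it did not pass (camera adjusted p = 0.293). There Svs1 and Svs5 did not pass with edgeR (adjusted p = 0.109 and 0.148), but passed with DESeq2 (0.000435 and 0.038), and Svs5 passed with limma-voom (0.0375). Svs2, with similar copies, was at 44853 ± 8712 CPM in the controls, 21296 ± 4543 after Ar deletion and 18667 ± 4566 after castration. Svs1 was at 32.6, 2258 and 28.5 CPM in the control libraries, 1580, 24.4 and 240 CPM in the Ar deletion libraries and 2.41 ± 2.7 CPM after castration, where it did not pass against the control (adjusted p = 0.0784). Endothelial markers rose for 1 and fell for 1 of 9 after Ar deletion (adjusted p = 0.765) and fell for 1 after castration (adjusted p = 0.456, median 0.03 and mean -0.29), as adjusted over the list alone, with Emcn down 7.38-fold and 6.01-fold. Neuroendocrine genes rose for 1 and fell for 2 of 5 in each (adjusted p = 0.979 and 0.765), as adjusted over the list alone. Erythrocyte genes fell for 3 of 5 after Ar deletion, against 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.16, but 0.0424 with fry and 0.0299 without the top basal library of each group), and rose for 1 after castration, with 0 adjusted over the list alone (adjusted p = 0.196, and 0.0224 without castration replicate 3).

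Where no other number is given here, the numbers adjusted over the list alone were the same. Among the other lists, p53 targets rose for 6 and fell for 3 of 16 after Ar deletion (adjusted p = 0.162) and for 7 and 1 after castration (adjusted p = 0.0839, and 0.0185 without castration replicate 3), the latter 8 and 2 adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, rose 2.72-fold and 2.37-fold. Apoptosis regulators rose for 9 and fell for 4 of 19 after Ar deletion (adjusted p = 0.293) and for 7 and 1 after castration (adjusted p = 0.16), where 8 rose adjusted over the list alone. Fatty acid synthesis genes rose for 2 and fell for 2 of 14 after Ar deletion (adjusted p = 0.979, median -0.08 and mean 0.07) and for 2 and 5 after castration (adjusted p = 0.291), the latter 2 and 7 adjusted over the list alone, with Fads2 up 3.46-fold and 2.24-fold. Polyamine genes rose for 3 and fell for 3 of 10 (adjusted p = 0.641) and for 2 and 3 (adjusted p = 0.703, median 0.02 and mean -0.04), with Srm, spermidine synthase, down by 0.94 ± 0.08 and 0.89 ± 0.08 on the log2 scale. Steroid receptors and cofactors rose for 5 and fell for 3 of 16 after Ar deletion (adjusted p = 0.815), where 6 rose adjusted over the list alone, and for 8 and 3 after castration (adjusted p = 0.16). Pgr, the progesterone receptor gene, rose from 0.620 ± 0.13 to 3.12 ± 0.71 and 1.66 ± 0.32 CPM. Wnt targets rose for 4 and fell for 3 of 12 after Ar deletion (adjusted p = 0.992, median 0.30 and mean 0.06 with the test downward). Ribosomal protein genes rose for 31 and fell for 2 of 83 after Ar deletion (29 and 2 adjusted over the list alone, adjusted p = 0.16) and for 10 and 0 after castration (2 and 0 adjusted over the list alone, adjusted p = 0.154). Mitochondrially encoded transcripts rose for 1 and fell for 7 of 10 (adjusted p = 0.0685, but 0.0202 with fry, 0.0249 without control replicate 3, 0.0405 without Ar deletion replicate 1 and 0.0493 without the libraries highest in Svs1) and for 2 and 7 (adjusted p = 0.344), with mt-Cytb down by 0.53 ± 0.09 in each and mt-Rnr2 up 1.55-fold and 3.98-fold. With fry some of these lists passed, namely p53 targets (adjusted p = 0.0117 and 0.0155) and apoptosis regulators (0.000657 and 0.000724) in both comparisons, ribosomal proteins after Ar deletion (0.0402), and fatty acid synthesis (0.00518) and steroid receptors (0.024) after castration.

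In castration versus Ar deletion, the lists not described above did not pass (camera adjusted p from 0.114 to 0.992). Of these, the endothelial list passed with fry (adjusted p = 0.0312) and without the top basal library of each group (0.0357), fatty acid synthesis with fry (0.00349), and mitochondrially encoded transcripts without the top basal library of each group (0.0439) or without castration replicate 2 (0.0476). Among these, median, mean and test differed in sign for secretory proteins (0.01 and -0.31, test downward), antigen presentation (-0.14 and -0.11, test upward), immediate early and stress genes (-0.03 and 0.05, test downward), p53 targets (0.05 and -0.07, test upward), apoptosis regulators (-0.07 and -0.01, test upward) and steroid receptors and cofactors (-0.02 and 0.08, test upward). For neuroendocrine genes after Ar deletion the median was -0.97 and the mean 0.09, with the test upward.

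Some features were chosen after their values were seen. Beside Sbp and Spink1, Ar deletion replicate 3 stood apart in Abo, which encodes a glycosyltransferase, at 10.7 against 102 and 89.5 CPM. It also stood apart in Spink5, at 1.81 against 28.9 and 30.7 CPM. The predicted gene Gm15772, a processed pseudogene, was at 111, 107 and 104 CPM in the Ar deletion libraries and between 1.09 and 1.39 CPM in the other 6. Gm13394, also a processed pseudogene, was at 52.0, 52.6 and 26.2 CPM against at most 0.232 CPM. Only the Ar deletion libraries came from mice with the floxed gene, so a difference between lines cannot be told apart from the deletion. CreERT2 was at 46.8% of the control mean after Ar deletion and 60.6% after castration.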
